A study of Mus musculus with 6 samples.

How the data were processed

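The samples are F4/80-positive peritoneal cells of C57BL/6 mice with the p16-Cre and Rosa26-mTmG alleles, kept for 12 months, per the labels. Cells were selected with magnetic beads and then sorted by flow cytometry into EGFP (p16High) and tdTomato (p16Low) fractions, and total RNA was sequenced, per the labels. The 6 libraries form 2 groups of 3. The labels do not state that the replicates of a group are separate animals, nor that replicate numbers pair the groups. The limma p-values of single genes therefore measure only the spread between these libraries.

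The deposited file is 1 table of FPKM values for 54532 genes, made by the authors from reads per gene, gene length and library total; raw reads were not used here. Bowtie2 2.2.3, TopHat2 2.0.12 and HTSeq 0.6.1 are listed per the submitters' processing notes, and the role and settings of each are not given in the sources used here. The genome build is not given in the sources used here. Of the deposited gene IDs, 54408 were found in GENCODE M21 (GRCm38) and 124 were not, and 98.3% of those found had the same start and end, so coordinates are given on GRCm38.

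Counts had been expected when the tests were planned, but the unit was FPKM. Count models were therefore not used here (edgeR and DESeq2 were not run), and limma was used instead. The groups, the contrast, the gene lists, the naming rule and most alternatives were fixed before the data were examined; the switch to limma, the FPKM filter and the alternatives marked as added later were not.

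Whole reads were worked back from the deposited FPKM values. With the annotated mean transcript length of each gene, 96.1% of the 22566 genes above 0 gave whole reads in every library within 0.001 of a read, and after a search over whole-number lengths 100% did. Of the searched genes, 593 allowed 1 length and 287 several, and the reads of the latter are uncertain by a factor. The library totals were 18.46, 20.87 and 20.15 M reads in p16Low and 18.94, 19.57 and 16.52 M in p16High. At these depths 3 reads over 1 library correspond to 0.144 to 0.182 CPM. Recovered reads served for depth, CPM, the limma-voom alternative and the counts of genes below the filter.

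Genes with FPKM of at least 1 in 3 or more libraries were tested, 10895 in all. Differences were tested on log2(FPKM + 1) with limma 3.58.1 (R 4.3.3), using an intercept and the group, empirical Bayes moderation with a trend, and Benjamini-Hochberg adjustment at 0.05. Every adjusted p of a single gene is from limma unless stated. Log2 fold changes are differences on that scale, folds are ratios of mean FPKM, and errors are the SD of 3 libraries or the SE of the log2 fold change. A pseudocount of 1 pulls the log2 fold change of low genes towards 0.

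The 32 gene lists were written from general knowledge of macrophage biology, and 24 had at least 5 tested members. Each was tested against all other tested genes with camera at an inter-gene correlation of 0.01, adjusted over the lists. Camera with an estimated correlation and fry were run beside it. The p-values at the preset correlation rest on the spread between genes and on that correlation, not on the spread between libraries alone. Members were also adjusted over their list alone. The lists covered cell cycle inhibitors and senescence regulators, secretory factors of senescence, proliferation, large and small peritoneal macrophages, MHC class II and class I presentation, interferon response, pro-inflammatory and alternative activation, NF-kB regulation, efferocytosis, cholesterol biosynthesis, lipid handling, glycolysis, oxidative phosphorylation, lysosome, NRF2 targets and the unfolded protein response. Quality lists held immediate early, heat shock, ribosomal, mitochondrially encoded and sex-linked genes. Lists of other cells held B, T and NK, mast, eosinophil, neutrophil, dendritic, mesothelial and stromal, and red cell and platelet genes. List members whose symbol occurs more than once in the table were left out. 1 member of the B-cell list counts in that list's values; it, and tests of B-cell loss as the cause of the MHC class II and proliferation differences that were run with it, are not reported here.

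Genes were named by a rule. It took Cdkn2a and up to 15 rises and 15 falls, ranked by log2 fold change and not by the ratio of mean FPKM. These came from genes past the threshold with no overlap between groups, a mean CPM of at least 5, and no predicted or pseudogene symbol. Of rises, 14 qualified. It also took up to 4 members with the smallest p of each list with 3 or more members past the threshold, the passing members of other lists, and the 3 most abundant members of each list of other cells. Other genes are examples of list members, or are said to be chosen after their values were seen.

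Alternatives were median-of-ratios scaling, no filter, a filter of 1 CPM in 3 libraries, limma-voom on recovered reads, the replicate number as a block, a pseudocount of 0.1, and each library left out in turn. Array weights, quantile normalization and removal of each library's trend on GC content and length were added after p16Low replicate 2 had been seen to stand apart. Markers of other cells below the filter were compared by reads with an exact binomial test against the library totals, adjusted over 53 markers, and again with each library left out, which was added after seeing the data; binomial and Fisher values cover counting error only, not the spread between libraries.

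The test was tried on simulated data made from p16High against p16Low: 10734 genes, 200 of them changed, at a dispersion of 0.02. Limma on log2(FPKM + 1) called 93% of genes changed 2-fold and 100% of those changed 4-fold, none with the wrong sign, and 15 unchanged genes, 7.2% of its calls. The median error of the log2 fold change was -0.096 and -0.196. Camera called 10 of 10 shifted lists and 0 of 90 random ones. The simulated genes varied independently and no library lay apart. The simulation therefore does not show how camera treats lists whose members vary together. In the data the estimated correlation reached 0.925 for the ribosomal list. Limma-voom called 98% and 100%, with 5.7% of its calls unchanged. Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9 read the table and drew the figures.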

Results

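Total RNA of peritoneal macrophages from 12-month-old mice was sequenced. The mice carried a p16-Cre driver and the Rosa26-mTmG reporter, in which membrane tdTomato is replaced by EGFP once Cre has acted. Peritoneal cells were selected on beads for F4/80, a surface protein of macrophages, and sorted into an EGFP fraction, called p16High, and a tdTomato fraction, called p16Low. Each fraction gave 3 libraries. The library totals read back from the deposited FPKM values ran from 16.52 M reads in p16High replicate 3 to 20.87 M in p16Low replicate 2. Between 16831 and 18211 genes were above 0 in a library. Lysozyme 2 (Lyz2) alone took 9.80% to 11.1% of the reads. The labels do not say whether the 3 libraries of a fraction came from separate animals. The limma p-values of single genes therefore measure the spread between these libraries only. List p-values from camera also rest on the spread between genes and on a preset correlation.

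p16Low replicate 2 lay apart from the other 5 libraries. It sat at 48.87 on the first principal component, which held 55.6% of the variance, while the others lay between -15.89 and -4.70. Its pairwise correlations of log2 expression with the other libraries were 0.955 to 0.965, against 0.982 to 0.989 among the other 5. The second component, with 19.1% of the variance, placed the 3 p16High libraries at 9 to 12.61 and the other 2 p16Low libraries at -18.02 and -17.74. The share of reads on mitochondrial genes was 1.08% in p16Low replicate 2 and 0.545% to 0.684% in the other 5.

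**Figure D1:**
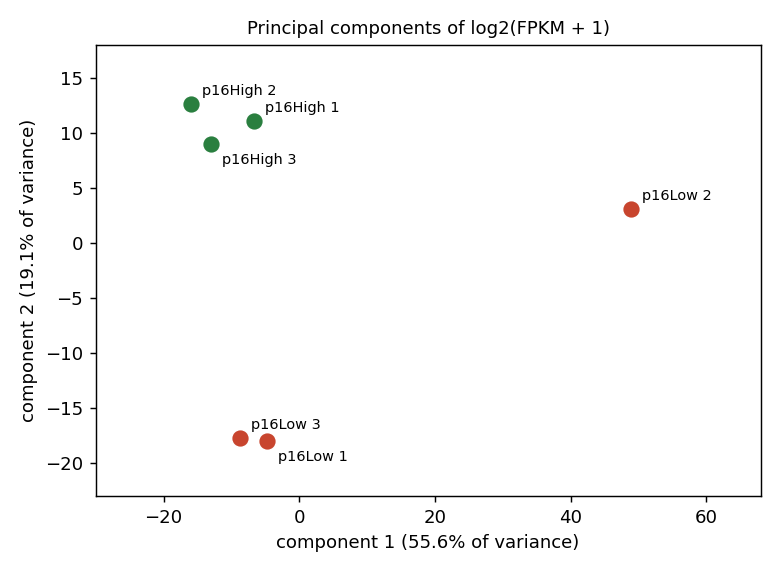
First 2 principal components of log2(FPKM + 1), 1 point per library, p16Low in red and p16High in green; the axes give each component's share of the variance. p16Low 2 lies alone at 48.87 on component 1, and component 2 separates the 3 p16High libraries from p16Low 1 and p16Low 3.

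The sort was checked first on Cdkn2a, the gene that encodes p16Ink4a. Cdkn2a stood at 6.78 ± 1.20 FPKM (SD, n = 3) in p16High and 1.09 ± 0.559 FPKM (SD, n = 3) in p16Low, a 6.24-fold difference. Its log2 fold change was 1.92 (SE 0.234, adjusted p = 0.0092 by limma), on the scale of log2(FPKM + 1), which understates changes of low genes. The read counts behind these values were 116, 134 and 79 in p16High and 10, 17 and 30 in p16Low. Cdkn2a (ENSMUSG00000044303) spans 89274471 to 89294653 on chromosome 4, minus strand, in coordinates that match the GRCm38 mouse assembly. The table gives 1 value for the whole gene, so its p16Ink4a and p19Arf transcripts were not told apart. Without p16High replicate 1 or p16High replicate 2 its adjusted p was 0.0698 and 0.0671, and over all alternatives it ran from 4.98e-06 to 0.114.

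Gm12606, a predicted gene of unknown function, was chosen after its values were seen, because it lies 1067 bp from Cdkn2a. It spans 89235699 to 89273403 on the same strand, beyond the 3' end of Cdkn2a, and stood at 3.42 ± 0.104 FPKM in p16High and 0.375 ± 0.0594 FPKM in p16Low (SD, n = 3; log2 fold change 1.69, SE 0.164, adjusted p = 0.00349). Of the 2 other neighbours, Cdkn2b, which encodes p15Ink4b, stood at 31.9 ± 1.87 FPKM against 20.7 ± 1.98 FPKM (log2 fold change 0.60, SE 0.143, adjusted p = 0.143). Mtap stood at 47.2 ± 2.69 FPKM against 40.1 ± 6.30 FPKM (adjusted p = 0.75).

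**Figure D2:**
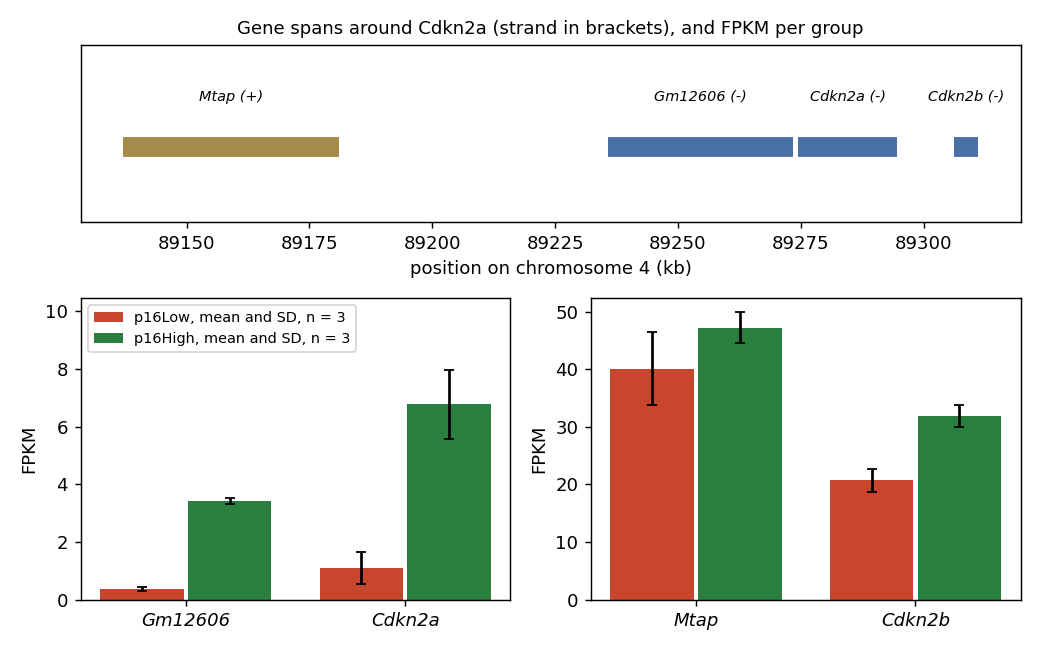
Spans of 4 genes on chromosome 4 in kilobases, with strand, above bars of their mean FPKM per group with the SD (n = 3), p16Low in red and p16High in green. Cdkn2a and Gm12606 stand at 6.78 and 3.42 FPKM in p16High against 1.09 and 0.375 FPKM in p16Low, beside smaller differences for Cdkn2b and Mtap.

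The comparison asked how gene expression differs between p16High and p16Low macrophages. Genes of cell division and 4 genes of antigen presentation by MHC class II were lower in p16High, and a smaller set, among them Fscn1 and Marco, was higher. Fscn1 (ENSMUSG00000029581, chromosome 5, 142960343 to 142973185), which encodes the actin-bundling protein fascin, stood at 79.8 ± 6.55 FPKM in p16High and 15.2 ± 3.54 FPKM in p16Low (SD, n = 3), 5.26-fold higher. Marco (ENSMUSG00000026390, chromosome 1, 120474538 to 120505024), a scavenger receptor of macrophages, stood at 491 ± 35.9 FPKM against 161 ± 12.2 FPKM, 3.05-fold higher. Stmn1, which encodes the microtubule regulator stathmin, stood at 8.13 ± 0.743 FPKM in p16High and 48.3 ± 10.8 FPKM in p16Low, 5.94-fold lower. Cd74 (ENSMUSG00000024610, chromosome 18, 60803848 to 60812646), the invariant chain of MHC class II, stood at 147 ± 9.93 FPKM against 399 ± 22.3 FPKM, 2.72-fold lower.

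Of 10895 genes tested with limma, 97 changed at a Benjamini-Hochberg adjusted p under 0.05, 19 of them higher and 78 lower in p16High, and 87 changed at least 2-fold. All 97 had no overlap between the groups' values. Among all tested genes 15.9% had none, where chance gives 10% for 3 libraries against 3. Without p16Low replicate 2, 301 genes changed, 97 higher and 204 lower, and all 97 genes found with 6 libraries were among them. The count was 26 without p16Low replicate 1, 32 without p16Low replicate 3, and 21, 17 and 25 without p16High replicates 1, 2 and 3.

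Besides Cdkn2a, Fscn1 and Marco, 12 genes made up the named rises. Nnmt, which methylates nicotinamide, had a log2 fold change of 1.29 (SE 0.206, adjusted p = 0.0327). Cd55, an inhibitor of complement, rose by 1.27 (SE 0.217, adjusted p = 0.0362). Cd63, a tetraspanin of late endosomes and lysosomes, stood at 304 ± 11.7 FPKM against 133 ± 19.5 FPKM, with a log2 fold change of 1.20 (SE 0.136, adjusted p = 0.00692). The processed copy Cd63-ps also rose (log2 fold change 1.098, adjusted p = 0.014; chosen after its values were seen), and reads can be split between the pair, so both values are uncertain. The C-type lectin gene Cd209b rose by 1.20, Tdo2, which encodes tryptophan dioxygenase, by 1.17, and the transporter gene Slc10a6 by 1.08. Asz1 and Tns1, which encodes tensin 1, rose by 1.01 and 0.96. AC168977.1 and AC133103.1 lie on unplaced scaffolds and rose by 1.06 and 0.98; both have related copies in the genome, such as C130026I21Rik, and are uncertain. Vsig4 and Cxcl13 are described with the macrophage markers. Of these 12 genes, none passed in every fit with 1 library left out. Without p16High replicate 1 or p16High replicate 2 none of the 12 passed. Without p16High replicate 3 none did either. Without p16Low replicate 1, Cd55 and Cd63 passed, and without p16Low replicate 3, Cd63 and Cd209b did. Without p16Low replicate 2 all 12 passed, with the largest adjusted p at 0.00291.

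Of the 35 genes on the proliferation list, 32 were tested and 17 fell, while none rose. Adjusted over the list alone, 30 fell, and all 32 had a negative log2 fold change, with a median of -1.28. The list moved as a set (camera, adjusted p = 7.28e-54), and it was the only list that also passed with an estimated correlation (adjusted p = 0.0387). Top2a, which encodes a DNA topoisomerase of dividing cells, fell from 18.1 ± 3.95 to 2.69 ± 0.410 FPKM (SD, n = 3), a log2 fold change of -2.36 (SE 0.199, adjusted p = 0.00197). Rrm2, a subunit of ribonucleotide reductase, fell by 2.37 on the log2 scale, and the thymidine kinase gene Tk1 fell by 2.13. Cdk1, the kinase that drives mitosis, stood at 5.80 ± 0.820 FPKM against 22.9 ± 3.88 FPKM. The 15 largest falls ran from a log2 fold change of -2.44 for Pclaf to -1.68 for Uhrf1, and beside these and those above they were Stmn1, Birc5, Ccna2, Spc24, Pbk, Cdca3, Ccnb2, Cdca7 and Ube2c. Of the 32 tested members, 29 fell without p16Low replicate 2 and 8 fell without any 1 of the other 5 libraries. Without p16High replicate 2, 6 of the 15 missed the threshold (Spc24, Pbk, Cdca3, Cdca7, Ube2c and Uhrf1); Spc24 also missed it without p16High replicates 1 and 3, Cdca3 without replicate 3 and Ube2c without replicate 1. Among the 6 fits with 1 library left out, Pbk, Cdca7 and Uhrf1 passed only without p16Low replicate 2.

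Of 12 tested genes on the list of MHC class II presentation, 4 fell and none rose; adjusted over the list alone, 5 fell. The 4 were Cd74, with a log2 fold change of -1.44 (SE 0.118, adjusted p = 0.00181), and the MHC class II chains H2-Aa, H2-Ab1 and H2-Eb1, which lie together on chromosome 17 between 34263209 and 34316199. H2-Aa stood at 97.3 ± 2.54 FPKM in p16High against 263 ± 25.1 FPKM in p16Low, and H2-Eb1 at 28.5 ± 0.790 FPKM against 85.3 ± 14.2 FPKM. H2-Ab1 had a log2 fold change of -1.28 (SE 0.115, adjusted p = 0.00237). The 4 passed in each of the 6 fits with 1 library left out. Some other members had values close to each other in both groups, such as Cd86 at 94.7 ± 5.92 FPKM against 87.6 ± 22.8 FPKM and H2-DMb1 at 44.2 ± 2.34 FPKM against 44.8 ± 2.80 FPKM. As a set the list was lower (camera, adjusted p = 5.64e-08), with adjusted p = 0.0699 with an estimated correlation.

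**Figure D3:**
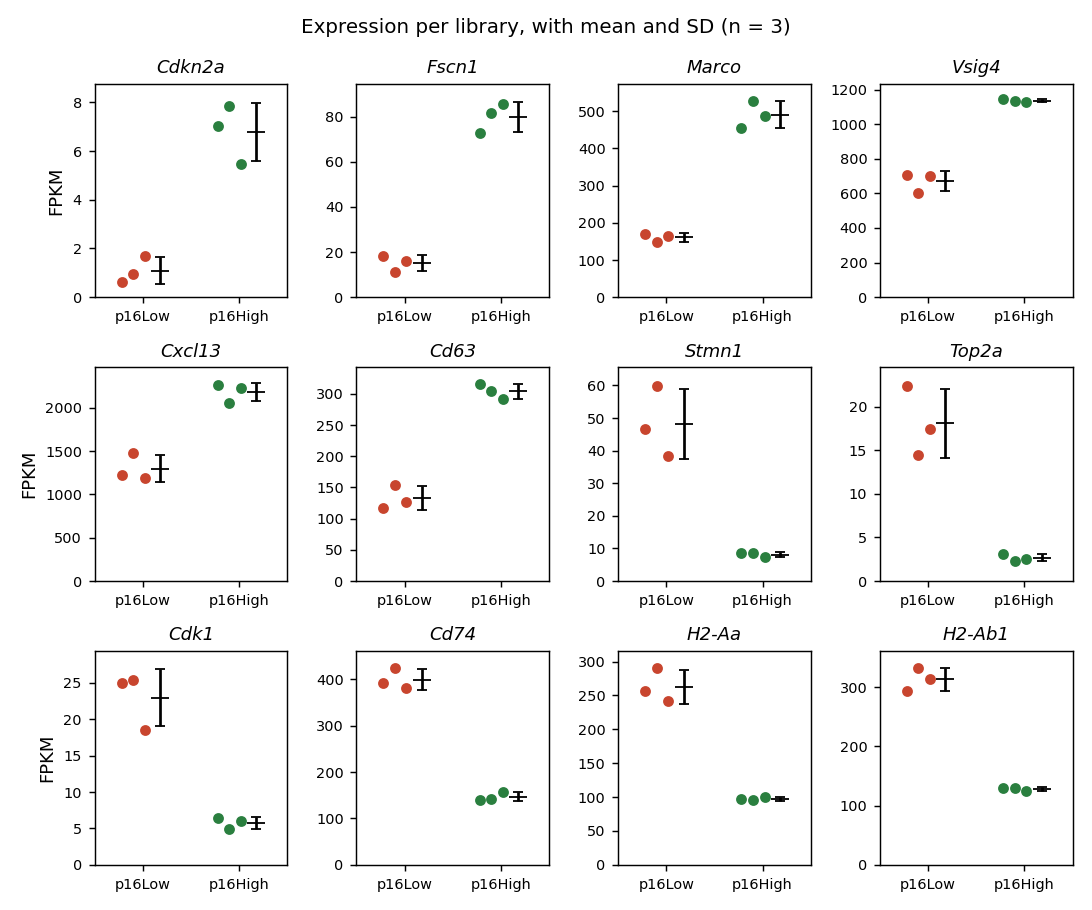
FPKM per library for 12 genes, 1 point per library, with the mean and SD (n = 3) in black beside the points; every vertical axis starts at 0. Cdkn2a, Fscn1, Marco, Vsig4, Cxcl13 and Cd63 were higher in all 3 p16High libraries, and Stmn1, Top2a, Cdk1, Cd74, H2-Aa and H2-Ab1 were lower in all 3.

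B-cell transcripts were measured beside these groups, because B cells share the peritoneal cavity. None of the 13 tested B-cell genes passed in limma over all genes, 8 had an unadjusted p under 0.05, and limma-voom called 0. Adjusted over the list alone, 8 were lower in p16High, and the list was lower as a set (camera, adjusted p = 2.77e-07), with adjusted p = 0.0699 with an estimated correlation. Without p16Low replicate 2, 3 of the 13 fell. Cd79a stood at 6.80 ± 1.56 FPKM in p16High and 13.1 ± 1.04 FPKM in p16Low, and Ms4a1, which encodes CD20, at 4.38 ± 0.697 FPKM against 8.66 ± 0.882 FPKM. The most abundant of the list were Bank1, at 30.9 ± 1.42 FPKM against 30.1 ± 4.91 FPKM, Ighm, at 28.8 ± 9.08 FPKM against 43.0 ± 5.18 FPKM, and Igkc, at 82.0 ± 25.8 FPKM against 122 ± 17.0 FPKM.

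Of 22 genes that mark large peritoneal macrophages, 2 rose and none fell, and 19 had a positive log2 fold change. The median over all tested genes was 0.051, so counts of positive members depend on the scaling. With median-of-ratios scaling 15 were positive and 7 negative. Vsig4, a complement receptor of resident macrophages, stood at 1136 ± 10.3 FPKM in p16High and 669.6 ± 58.6 FPKM in p16Low (log2 fold change 0.77, SE 0.116, adjusted p = 0.0255). Cxcl13, a chemokine that attracts B cells, stood at 2183 ± 108 FPKM against 1297 ± 154 FPKM (log2 fold change 0.76, SE 0.126, adjusted p = 0.0351). The transcription factor gene Gata6 stood at 32.3 ± 1.28 FPKM against 28.45 ± 4.34 FPKM. The same 2 rose when adjusted over the list alone; over all genes both passed without p16Low replicate 2, where Thbs1 also fell, and neither without any 1 of the other 5 libraries. Vsig4 also missed the threshold with quantile normalization, Cxcl13 with median-of-ratios scaling, and both with no filter and with a replicate block; over all alternatives their adjusted p ran from 6.08e-06 to 0.184 and from 2.69e-06 to 0.225. The list was higher as a set (camera, adjusted p = 0.00162), with adjusted p = 0.308 with an estimated correlation.

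Of 16 tested genes that mark small peritoneal and monocyte-derived macrophages, none passed in limma over all genes, 6 had an unadjusted p under 0.05, and limma-voom called 0. Adjusted over the list alone, 4 were lower in p16High, among them Plac8 at 7.62 ± 2.28 FPKM against 18.3 ± 3.76 FPKM and Chil3 at 17.25 ± 2.198 FPKM against 39.5 ± 10.0 FPKM. The list was lower as a set (camera, adjusted p = 0.010), with adjusted p = 0.179 with an estimated correlation, although 7 members had a positive log2 fold change and its median was -0.10. The median was -0.21, -0.17 and 0.00 without p16Low replicates 1, 2 and 3 and -0.20 without p16High replicate 3. The fit without p16Low replicate 2 had 4 falls, Plac8, Chil3, Napsa and S100a4.

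On the lysosome list, Cd63 was the 1 gene of 33 that rose, and 32 had a positive log2 fold change, with a median of 0.31. With median-of-ratios scaling 30 were positive. Ctsd, which encodes cathepsin D, stood at 3020 ± 108 FPKM in p16High and 2067 ± 329 FPKM in p16Low (adjusted p = 0.189). The list was higher as a set (camera, adjusted p = 7.39e-11), with adjusted p = 0.308 with an estimated correlation. When adjusted over the list alone, Cd63 was again the 1 that rose. Without p16Low replicate 2 the median was 0.17 and 8 of the 33 rose, and without p16High replicate 1, 2 or 3 none did.

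Of 24 cell cycle inhibitors and senescence regulators, Cdkn2a rose and Uhrf1, which maintains DNA methylation, fell, and the list did not move as a set (camera, adjusted p = 0.512). Adjusted over the list alone, 2 were higher, Cdkn2a and Cdkn2b, and 2 lower, Uhrf1 and Ezh2; Ezh2 stood at 3.87 ± 0.745 FPKM against 8.57 ± 1.76 FPKM. Its adjusted p was 0.54 with an estimated correlation. Cdkn1a, which encodes p21, stood at 57.1 ± 3.41 FPKM against 66.7 ± 18.2 FPKM (adjusted p = 0.782). None of 21 tested secretory factors associated with senescence passed in limma, 4 had an unadjusted p under 0.05, limma-voom called 0, and the list did not move as a set (camera, adjusted p = 0.334). Igfbp4 was lower when adjusted over the list alone, at 39.2 ± 1.75 FPKM against 67.7 ± 10.8 FPKM. Il6 stood at 3.45 ± 0.817 FPKM against 4.79 ± 1.03 FPKM, Il1a at 6.98 ± 0.708 FPKM against 5.78 ± 2.61 FPKM, and Spp1 at 38.7 ± 0.720 FPKM against 28.4 ± 1.27 FPKM. In the fit without p16Low replicate 2, 2 secretory factors rose and 1 fell, and on the list of inhibitors and regulators 3 rose and 3 fell.

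**Figure D4:**
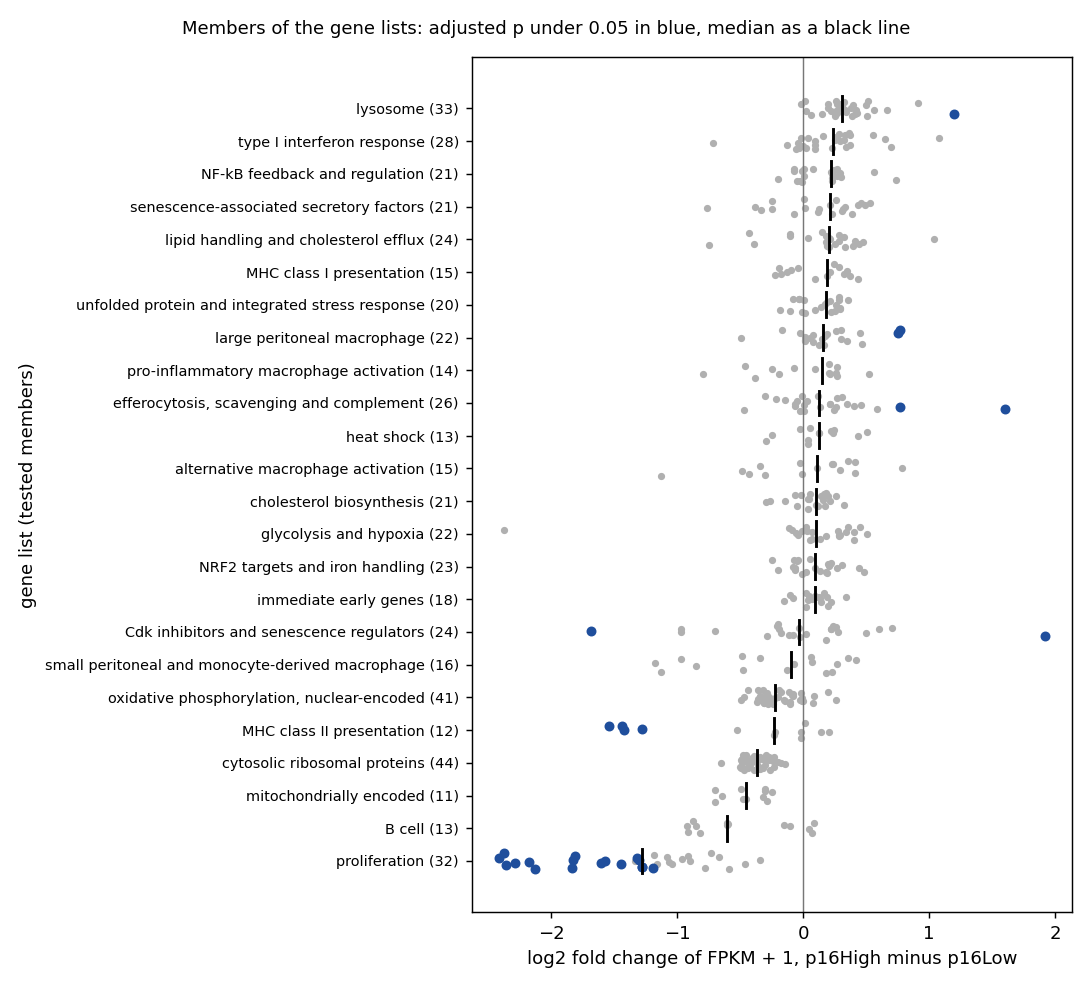
Log2 fold change of each tested member of 24 gene lists, 1 point per gene, p16High minus p16Low on the horizontal axis and lists on the vertical axis with their tested members in brackets; blue marks an adjusted p under 0.05 over all genes and the black line the median of the list. The proliferation list has 17 blue points, all below 0, and the list of MHC class II presentation has 4.

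The 7 other lists that moved as a set in camera held few changed genes. Type I interferon response was higher, with 22 of 28 members positive (adjusted p = 0.00523; adjusted p = 0.151 with an estimated correlation); Irf7, a transcription factor of that response, stood at 53.6 ± 2.66 FPKM in p16High and 33.3 ± 7.595 FPKM in p16Low. Lipid handling and cholesterol efflux was higher (adjusted p = 0.0182; adjusted p = 0.37 with an estimated correlation), with 19 of 24 members positive. Adjusted over that list alone, Gpnmb was higher, at 10.2 ± 0.457 FPKM against 4.61 ± 1.53 FPKM, and Fabp5 lower, at 61.2 ± 5.60 FPKM against 105.5 ± 27.0 FPKM. The unfolded protein response was higher (camera, adjusted p = 0.0475, and adjusted p = 0.37 with an estimated correlation), with 15 of 20 members positive. With median-of-ratios scaling 19 of 28 interferon, 19 of 24 lipid and 13 of 20 unfolded protein members were positive. No member of these 3 lists passed in limma or limma-voom; 4, 6 and 0 had an unadjusted p under 0.05. In the fit without p16Low replicate 2, Irf7 and Oasl1 rose and Ifi27l2a fell on the interferon list, and 1 member of the lipid list rose and 2 fell. Efferocytosis, scavenging and complement was higher (adjusted p = 0.048; adjusted p = 0.54 with an estimated correlation), with Marco and Vsig4 as the 2 of 26 that rose, over all genes and over the list alone; 1 other member fell without p16Low replicate 2, and Marco alone passed without any 1 of the other 5 libraries. Without p16Low replicate 1 the call on lipid handling was lost (adjusted p = 0.0825), and that on efferocytosis was lost in 10 of 15 alternatives, among them limma-voom (0.0607) and the fits without p16Low replicate 2 (0.167) and p16High replicate 2 (0.105). Across all alternatives these 2 lists had adjusted p of 0.00202 to 0.0825 and 0.023 to 0.276. The call on the unfolded protein response held without p16Low replicate 2 and was lost in 8 of 15 alternatives, among them the fits without p16Low replicates 1 and 3 (0.0731 and 0.119) and p16High replicates 1, 2 and 3 (0.0936, 0.0655 and 0.0597), within a range of 0.00529 to 0.119.

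Cytosolic ribosomal proteins were lower in p16High as a set (camera, adjusted p = 1.45e-13; adjusted p = 0.37 with an estimated correlation), with all 44 members negative and a median of -0.37. Nuclear-encoded oxidative phosphorylation was lower (adjusted p = 6.11e-06; adjusted p = 0.37 with an estimated correlation), with 36 of 41 members negative. Mitochondrially encoded genes were lower (adjusted p = 1.15e-08; adjusted p = 0.242 with an estimated correlation), with all 11 negative; adjusted over that list alone, mt-Cytb was lower, at 671.5 ± 66.0 FPKM against 932.6 ± 10.8 FPKM. No gene of these 3 lists passed in limma; 4, 1 and 8 had an unadjusted p under 0.05, and limma-voom called 0. p16Low replicate 2, the library that lay apart, held the highest value for 43 of the 44 ribosomal genes, 34 of the 41 and 9 of the 11. Without it the ribosomal median was -0.083, with 5 of the 44 positive, and 3 mitochondrially encoded genes fell, mt-Cytb, mt-Nd4 and mt-Nd6. The call on oxidative phosphorylation was then lost, with a median of -0.048 in place of -0.223 (adjusted p = 0.127, in a range of 4.44e-08 to 0.127 over all alternatives).

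The remaining 9 lists did not move as a set. Their adjusted p from camera was 0.067 for NF-kB regulation, 0.11 for glycolysis and hypoxia, 0.235 for immediate early genes, 0.239 for MHC class I presentation and 0.255 for heat shock. It was 0.36 for NRF2 targets, 0.488 for pro-inflammatory activation, 0.521 for cholesterol biosynthesis and 0.909 for alternative activation. Glycolysis and hypoxia passed with no filter (adjusted p = 0.0311, in a range of 0.0311 to 0.614), and MHC class I presentation and heat shock passed in fry (adjusted p = 0.042 and 0.0248). No member of these lists passed in limma or limma-voom; 2, 3, 2 and 6 members of the NF-kB, glycolysis, pro-inflammatory and alternative activation lists had an unadjusted p under 0.05, and 0 of the other 5. The fit without p16Low replicate 2 called 3 members of alternative activation and 1 each of the NF-kB, pro-inflammatory, NRF2 and immediate early lists, and that without p16Low replicate 3 called 1 of glycolysis. Adjusted over its own list, Il1rn, the interleukin 1 receptor antagonist, was higher, at 7.56 ± 1.19 FPKM against 4.12 ± 0.238 FPKM. So was Arg1, which encodes arginase 1, at 1069 ± 22.6 FPKM against 802.9 ± 27.9 FPKM, while Chil3 and the formyl peptide receptor gene Fpr1, at 25.7 ± 3.13 FPKM against 45.2 ± 3.57 FPKM, were lower. Pro-inflammatory activation had a median of 0.15, a mean of -0.01 and a camera direction of lower; without p16Low replicate 2 its median was -0.13. Without p16Low replicate 2 the lists of MHC class I presentation, NF-kB regulation and NRF2 targets were higher as sets (adjusted p = 0.00922, 0.0399 and 0.0388); over all alternatives they ran from 0.00922 to 0.615, 0.0171 to 0.463 and 0.0388 to 0.663.

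Of the lists for other cell types, all but the B-cell list had fewer than 5 tested members and were not tested as sets with the filter of the main test. Looser filters brought more members in. With no filter the mast cell list (7 members, camera, adjusted p = 0.000128) and the dendritic cell list (12 members, adjusted p = 0.0075) were higher in p16High. The dendritic cell list was also higher with the 1 CPM filter (5 members, camera, adjusted p = 0.00018). Its median log2 fold change with no filter was only 0.084, with 9 members positive, 3 negative and 1 past the threshold. With no filter the T and NK, eosinophil, neutrophil, mesothelial and stromal, and red cell and platelet lists did not move as sets (adjusted p = 0.21, 0.774, 0.558, 0.317 and 0.317). Fscn1 was the 1 changed gene of 4 tested on the dendritic cell list; Cd24a stood at 306 ± 17.2 FPKM in p16High against 288 ± 12.8 FPKM in p16Low, and Cd209a at 18.2 ± 4.63 FPKM against 8.36 ± 0.848 FPKM (adjusted p = 0.0729). Of T and NK cell genes, Cd2 alone was tested, at 5.20 ± 0.369 FPKM against 8.86 ± 1.20 FPKM, and Cd3g had 5 reads in p16High and 11 in p16Low. Of mast cell genes, Hdc alone was tested, at 98.1 ± 1.84 FPKM against 75.4 ± 18.4 FPKM. Of eosinophil genes, Alox5 alone was tested, at 214 ± 24.0 FPKM against 168 ± 50.5 FPKM, and Ccr3 had 61 reads in p16High and 45 in p16Low. The neutrophil genes Csf3r, S100a8 and Lcn2 had adjusted p of 0.772, 0.759 and 0.973. No mesothelial, stromal, red cell or platelet gene reached the filter, where Pecam1 had 63 reads in p16High and 36 in p16Low, Krt18 10 and 4, Kdr 3 and 2, Gp9 0 and 12, Itga2b 10 and 1, and Ppbp 1 and 6. None of the 4 tested sex-linked genes passed in limma or in limma-voom, and none had an unadjusted p under 0.05.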

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

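Each result given first here is a marker of another cell type that lies below the filter of the main test and had more reads in p16High than in p16Low (exact binomial test, adjusted over 53 markers). These tests, and the same tests with 1 library left out, were chosen only after the files had been read. They cover counting error only. Where p16Low had 0 reads, the fold given is the p16High rate over that of 3 reads in p16Low. That fold leaves out the counting error of the p16High reads, so it is not a lower bound. In all, 8 markers were higher in p16High and 7 lower, and on 3 lists markers went both ways.

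The mast cell protease gene Cma1 had 36 reads over the 3 p16High libraries (12, 9 and 15) and 0 in p16Low (exact binomial, adjusted p = 1.85e-10). Set against 3 reads this was 13-fold, and 8.4-fold to 15.1-fold with 1 library left out, the lowest without p16Low replicate 2. Tpsb2 and Mcpt4 had 17 reads (1, 3 and 13) and 14 reads (0, 5 and 9) and 0 in p16Low, or 6.1-fold and 5-fold against 3 reads. With 1 library left out these folds ran from 2.1-fold to 8.8-fold and from 2.6-fold to 7.7-fold, the lowest without p16High replicate 3. Cpa3 had 43 reads in p16High and 5 in p16Low, a ratio of 9.3 (95% interval 3.69 to 30.1), and 6.15 to 32.05 with 1 library left out.

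Among T and NK cell markers, Il7r had 13 reads in p16High (3, 0 and 10) and 0 in p16Low, or 4.7-fold against 3 reads. With 1 library left out this fold ran from 1.5-fold to 7.3-fold. The lowest was without p16High replicate 3, where the test did not pass (exact binomial p = 0.0607). Lck went the other way, with 0 reads in p16High and 9 in p16Low (2, 0 and 7; exact binomial, adjusted p = 0.0182), and 2 reads without p16Low replicate 3 (exact binomial p = 0.174). Among dendritic cell markers, Zbtb46 had 193 reads in p16High (33, 82 and 78) and 116 in p16Low (39, 36 and 41). The ratio was 1.8 (95% interval 1.42 to 2.3), but p16High replicate 1 showed no rise. Ccr7 had 16 reads in p16High (8, 1 and 7) and 52 in p16Low (15, 10 and 27), a ratio of 0.33 (95% interval 0.18 to 0.6). Pecam1, an endothelial marker, had 63 and 36 reads, a ratio of 1.89 (95% interval 1.24 to 2.9), and 1.35 without p16High replicate 2 (exact binomial p = 0.249) and 1.43 without p16Low replicate 2 (exact binomial p = 0.116). Among platelet markers, Itga2b had 10 reads (3, 7 and 0) and 1 read, a ratio of 10.81 (95% interval 1.54 to 469.1), and 7.02, 7.15 and 5.03 without p16Low replicate 2, p16Low replicate 3 and p16High replicate 2 (exact binomial p = 0.0327, 0.0317 and 0.15). Without p16Low replicate 1, p16Low had 0 reads of Itga2b, and the fold against 3 reads was 2.5. Gp9 went the other way, with 0 reads in p16High and 12 in p16Low (exact binomial, adjusted p = 0.00323). The other markers lower in p16High were the B-cell genes Ebf1, Fcrl5 and Cr2 and the neutrophil gene Mmp8, of which only Fcrl5 kept an exact binomial p under 0.05 with every library left out. Ebf1 had ratios of 0.84 without p16Low replicate 1 and 0.89 without p16High replicate 2 (exact binomial p = 0.534 and 0.608), and 0.22 without p16High replicate 1 (exact binomial p = 1.01e-06), against 0.57 with all libraries. Cr2 had 0.5 without p16Low replicate 2 and 0.57 without p16High replicate 1 (exact binomial p = 0.0993 and 0.138), and 0.12 without p16High replicate 2 (exact binomial p = 0.000127), against 0.37, and Mmp8 had 0.75 without p16Low replicate 1 (exact binomial p = 0.282) against 0.48.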

How the results depend on the processing

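Array weights, quantile normalization and removal of the GC and length trend were added after seeing the data. The planned edgeR and DESeq2 fits were not run, since the values are FPKM. None of the 34 named genes changed direction under any alternative. All of them had no overlap between the groups, so leaving a library out could not change their direction. Counts of genes and lists have no direction and could not reverse, and they moved as given below.

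With 1 library left out, the genes changed ran from 17 (without p16High replicate 2) to 301 (without p16Low replicate 2), those higher from 3 to 97, those lower from 14 to 204 and those changed at least 2-fold from 17 to 142; fewer samples lower the power, and the cause of the rise to 301 was not tested. The log2 fold change of Cdkn2a ran from 1.75 to 2.12. With no filter, 9 genes changed, 2 higher, 7 lower and 9 at least 2-fold, and Cdkn2a had 1.92 with an adjusted p of 0.114; 22566 genes were then tested in place of 10895. Array weights gave 645 genes, 251 higher, 394 lower and 155 at least 2-fold. The weight was 0.105 for p16Low replicate 2, 4.181 for p16Low replicate 1 and 0.878 to 1.597 for the others. p16Low replicate 2 thus counted little in this fit, and whether that alone gave the rise to 645 was not tested. With the replicate number as a block 9 genes were higher and 67 changed. Whether the numbers pair the samples is not known. Deviations from the group mean correlated at -0.189, -0.173 and 0.014 between same-number libraries. Between libraries of different number they correlated at -0.196 to 0.244. With 3 libraries per group these values are too few to decide on pairing. Under median-of-ratios scaling, the 1 CPM filter, limma-voom, a pseudocount of 0.1, quantile normalization and trend removal, 88 to 145 genes changed.

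Of the 24 tested lists 13 moved as a set, and 11 to 14 of these 24 under the other settings. With no filter 32 lists were tested and 15 passed, among them mast and dendritic cells, and with the 1 CPM filter 13 passed, among them dendritic cells. Of the 24, 1 passed with an estimated correlation in camera, which allows for members that vary together. The estimate lay below the preset 0.01 for interferon response (-0.007) and small peritoneal macrophages (-0.014). Both lost their calls, so members that vary together do not account for the loss there. With fry, which tests a list against no change and not against other genes, 7 passed. These were proliferation, MHC class II, small peritoneal macrophages, interferon response and B cells, and MHC class I and heat shock, which camera did not call. The other lists called by camera did not pass with fry (adjusted p from 0.0665 to 0.339). Of the 34 named genes, 15 passed in all 6 fits with a library left out and 19 did not. Of the 33 besides Cdkn2a, 24 missed the threshold with no filter, 8 with the block, 4 with quantile normalization (Nnmt, Asz1, AC133103.1 and Vsig4), 1 with limma-voom (Cdca7) and 1 with median-of-ratios scaling (Cxcl13). Depth limits genes below 1 FPKM, which the main test leaves out.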

Other observations

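Genes of C-type lectins on chromosome 8 were chosen after their values were seen, and 2 of them passed, Clec4g and Cd209b. Clec4g rose (101 reads in p16High and 21 in p16Low, log2 fold change 0.985, adjusted p = 0.0362 by limma). Cd209a had 994 and 501 reads (adjusted p = 0.0729) and Cd209d 102 and 43 (adjusted p = 0.329), beside the rise of Cd209b with 2287 and 1040. Cd209f had 109 reads in p16High and 265 in p16Low (adjusted p = 0.364), and Cd209g, below the filter and not tested, 14 and 99.

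The genes in this paragraph were also chosen after their values were seen, and all but Ccr2 and Gapdh are on no gene list. Ccr2 is on the list of small peritoneal and monocyte-derived macrophages, and Gapdh on that of glycolysis and hypoxia. Clec4a2, an inhibitory lectin receptor gene, stood at 3.00 ± 0.675 FPKM in p16High and 8.69 ± 1.82 FPKM in p16Low (log2 fold change -1.28, adjusted p = 0.0335 by limma). Fcrls, Plp2 and Ms4a6c had log2 fold changes of -1.28, -1.11 and -0.901, all past the threshold, and Tmem176b stood at 144.8 ± 7.66 FPKM against 231.9 ± 17.3 FPKM (adjusted p = 0.0431). Ccr2, the chemokine receptor of monocytes, had 28 reads in p16High and 187 in p16Low. It lay below the filter of the main test and was left out of that test. Gapdh varied between libraries of the same group: 462, 546 and 30 reads in p16Low and 35, 33 and 12 in p16High (adjusted p = 0.469). Gapdh has many pseudogenes, and the sharing of reads with them was not checked, so these counts are uncertain.

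All tests in the paragraphs that follow were chosen only after the result was seen. The deciding rules of 2, on other-cell RNA in p16Low replicate 2 and on Gm12606, were changed after a first value had been seen, and both verdicts became undecided.

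p16Low replicate 2 stood apart from the other 5 libraries. Its deviation from the others followed transcript length (Spearman rho -0.424 over 10895 genes, against 0.071 to 0.245 in the other 5), so a technical difference tied to transcript length may account for part of it. RNA of other cell types cannot be told apart from no such change: the median deviation of 23 markers was -0.112, with 9 upward, and members go both ways. No biological explanation was tested.

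The 4 MHC class II genes were lower in p16High. A trend on GC content and length is argued against, since the mean was -1.464 with the trend removed and -1.419 before, with all 4 past the threshold (limma, largest adjusted p = 0.00231). Whether a lower share of small peritoneal and monocyte-derived macrophages plays a part cannot be decided from its list. The list was lower in camera in 15 alternatives (adjusted p from 0.00165 to 0.0412) and in fry (adjusted p = 0.023). It did not pass in camera with an estimated correlation (adjusted p = 0.179). The median was only -0.1, with 9 members down and 7 up, and from -0.209 to 0.002 with 1 library left out. Ccr2, a member of that list below the filter and so not in this median, had fewer reads in p16High. Its counts were 9, 10 and 9 in p16High and 68, 46 and 73 in p16Low. With no filter 13 of 22 members were down and 9 up, and the median was -0.099. A loss of B cells, and the difference between p16High and p16Low cells themselves, which was not tested, stay open.

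The proliferation genes were lower in p16High. A trend on GC content and length is argued against, since 20 members passed with the trend removed and 17 before. A loss of cells of another type stays open, as does the difference between p16High and p16Low cells, which was not tested.

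The hypothesis that transcription running on from Cdkn2a could give the reads of Gm12606 was tested on 622 reads. Gm12606 had 0.641 reads per read of Cdkn2a in p16High and 0.439 in p16Low, a ratio of 1.46 (exact 95% interval 0.87 to 2.52; Fisher's exact p = 0.144). The reads are too few to decide, and a shared control of both genes was not tested.

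The 6 libraries allow 10 splits into 3 and 3, which cannot give a share under 0.05. The real split was the 1 with the largest count of 97 genes changed, 19 higher, 78 lower and 87 at least 2-fold, where the highest other split had 0 in limma; the other 9 splits had 129 to 437 genes with an unadjusted p under 0.05. For lists the real split had 13 and the other 9 splits had 3 to 6.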
